A study of Homo sapiens with 10 samples.

How the data were processed

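RNA of K562, Lucena 1 and FEPS cells had been hybridized to Affymetrix Human Genome U133 Plus 2.0 arrays, 10 arrays in 5 groups of 2. The deposited table holds log2 signals of 54675 probe sets on the 10 arrays, with at most 2 decimals and values from 0.12 to 14.14. According to the submitters' processing notes, the authors made these values with Affymetrix Expression Console. The version, the summary method and the background correction are not given in the sources used here. Scans and raw intensities were not used here. All 10 columns were mapped to a sample by their labels, and 0 were left over.

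The log2 values as deposited were not on a common level, since array medians ran from 2.07 to 4.98, a range of 2.91. Use of the values as deposited had been written down before the data were examined. That choice was changed before any test was run: quantile normalization, one of the alternatives written down beforehand, became the main setting, and the values as deposited became an alternative. Quantile normalization gives every array the same distribution, so a change of most genes in one direction cannot be seen in it.

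Of the probe sets, 62 controls were left out, 41091 carried 1 gene symbol, 1801 carried several and 11721 had none given. Only probe sets with 1 symbol were used. The gene IDs of 41037 of them matched the human reference gene table (GRCh38.p14), and 54 did not. The labels state no genome build, so that table served only for names and for the order of genes along chromosomes, and no coordinates are given. To keep sex-linked markers out, 58 probe sets of XIST and of Y chromosome genes were removed. Of the 19741 genes left, 10511 had more than 1 probe set, and each gene was represented by the probe set with the highest mean over all arrays. For 5780 genes that probe set carried the suffix _x_at or _s_at, which marks sequence shared between transcripts. No filter on dim genes was applied.

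One limma model (lmFit and eBayes) with a mean per group and no covariate was fitted to all 10 arrays, which leaves 5 residual degrees of freedom. The 5 comparisons that the series describes and 1 interaction were tested with limma's two-sided moderated test. P-values were adjusted by Benjamini and Hochberg over all 19741 genes, and a gene was called at an adjusted p under 0.05. A group mean under 3.95, the median of all probe sets after normalization, was treated as background. Folds against such a group were computed with each of its array values under the median set to the median, and are lower bounds. Floored list medians were computed with group means set to it. With 2 arrays per group, no exact permutation test can reach a p under 0.05, and the number of arrays limits the precision. The replicate numbers were checked for pairing through the correlation of deviations from group means between arrays of the same number.

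Lists of genes, 26 in number, were fixed before the data were examined. They cover drug efflux transporters, genes flanking ABCB1, erythroid, megakaryocyte, and granulocyte and monocyte genes, lymphoid and fibroblast or epithelial markers, tubulin and microtubule genes, topoisomerases and DNA repair, p53 targets, apoptosis, glutathione and detoxification, DNA replication, mitosis, ER stress and amino acid response, cholesterol synthesis, interferon response, histones, heat shock, glycolysis and hypoxia, oxidative phosphorylation, lysosome, adhesion and mesenchymal genes, BCR-ABL, STAT5 and ERK targets, cancer-testis antigens and ribosomal proteins. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Of 130 list tests, 26 were past the preset test and 0 with an estimated correlation. The directional and the mixed test of fry, which do not compare a list with other genes, were run beside them. Members were counted as risen, fallen or not past the gene test, adjusted over all genes and adjusted over the list alone.

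Genes were named by a rule fixed beforehand. It takes up to 8 largest rises and 8 largest falls per comparison among called genes whose arrays do not overlap between groups, and up to 4 called members with the largest change per list. Any efflux transporter or gene flanking ABCB1 may be named, ABCB1, ABCC1, ABCG2, TOP2A, TOP2B and MVP are given whether or not they pass, and for the overlap the 8 largest shared rises and falls by the smaller change are named. The overlap was set beside the product expected from independent lists and beside 100 simulations of unchanged groups that share the same K562 arrays.

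The alternatives fixed beforehand were the values as deposited, arrays centred on their medians, filters on the mean or on the highest group mean, the mean of a gene's probe sets, probe sets without shared-sequence suffixes, a fit of only the groups compared, an intensity trend in the variance prior, a replicate block, a 2-fold minimum, each array left out in turn, and the other list tests. Added after the data were seen were a replicate block for K562 and Lucena 1 only and the ACTB 3′ minus 5′ difference as a covariate. Where 1 array of a group was left out, the lone array was assumed to vary like the other groups. In the setting without shared-sequence suffixes, a gene with only suffixed probe sets kept its brightest one, so its values there are those of the main setting.

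The fit was tested on simulated data with the spread of these arrays, taken as unpaired, and 200 changed genes of 19741. For Lucena 1 against K562 it recovered 17.9% of changes of 1, 92.5% of changes of 2 and 97% of changes of 3 on the log2 scale, with 9 false calls. For FEPS against K562 the shares were 13.4%, 89.6% and 97%, with 11 false calls. For the vincristine comparison they were 17.9%, 91% and 100%, with 10 false calls, and for the daunorubicin comparison 7.5%, 92.5% and 97%, with 8 false calls. In the data the comparisons with K562 called far more than 200 genes. With more true changes the adjusted threshold is looser, so the shares for these comparisons may be too low. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.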

Results

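RNA from 3 related leukemia cell lines was measured on Affymetrix Human Genome U133 Plus 2.0 arrays. K562 is a drug-sensitive line from a human chronic myeloid leukemia. Lucena 1 and FEPS are multidrug-resistant lines that descend from K562. Lucena 1 was selected with vincristine, which binds tubulin, and FEPS with daunorubicin, an anthracycline that acts on topoisomerase II. The 10 arrays formed 5 groups of 2: K562, Lucena 1 with 60 nM vincristine, Lucena 1 kept for 7 days without vincristine, FEPS with 466 nM daunorubicin, and FEPS kept for 7 days without daunorubicin. The small number of arrays limits the precision of every comparison. The labels do not say whether the arrays of a group came from separate cultures, so each p-value below measures only the spread between these arrays, which may be technical.

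The deposited log2 values were not on a common level, since the median of all probe sets ran from 2.07 on K562 replicate 1 to 4.98 on FEPS without drug replicate 2. They were quantile normalized before any comparison between lines, and counts from the values as deposited stand beside the normalized ones where they differ. After normalization the median of all probe sets was 3.95, and a signal under it was treated as background, so a fold against such a group is given as a lower bound. Genes called the largest below were ranked by fitted difference, so where a group lay under background their order is uncertain. Errors after ± are standard errors (SE) of a log2 difference from the limma fit, with n = 2 arrays in every group. In all 305 named gene results past the test both arrays of one group lay above both arrays of the other, which the naming rule itself required of the largest changes. For called gene lists, a second pair of counts adjusted over the list alone is given where it differs from the first. No called list turned its direction relative to all genes as deposited. Control RNAs with poly-A tails, added before target preparation, had median deposited signals of 5.56 to 6.59 on the 6 arrays of K562 and Lucena 1 and of 2.68 to 3.65 on the 4 FEPS arrays. The ACTB 3′ minus 5′ difference, which widens as RNA degrades, was 0.91 to 1.11 on the FEPS arrays and 0.94 to 2.67 on the other arrays. For GAPDH it was 0.1 to 0.28 and 0.04 to 0.35, and the covariate for RNA integrity below is that of ACTB alone. Hybridization controls had a median deposited signal of 6.05 on K562 replicate 1 and of 8.635 to 9.745 on the other arrays. After normalization it was 7.63, against 8.63 to 9.78. The poly-A signal points to a separate preparation of the FEPS arrays, which no label states. That preparation could not be told apart from the line in any comparison of FEPS with another line.

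**Figure D1:**
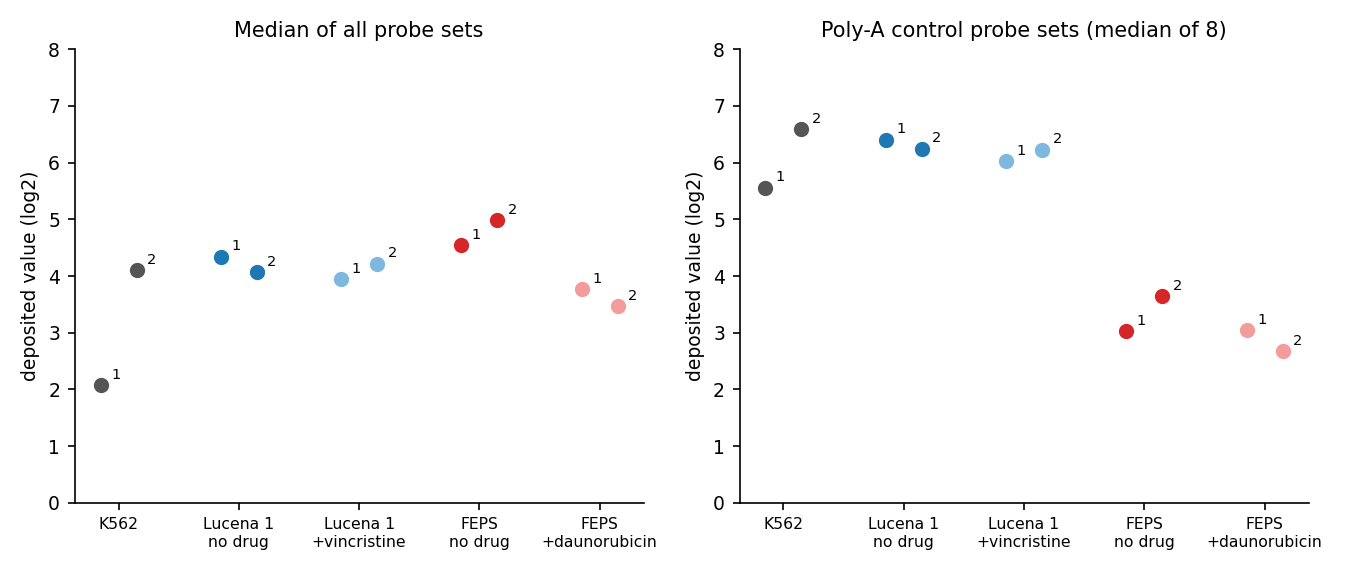
Median deposited signal (log2) of all probe sets and of the 8 poly-A control probe sets on each of the 10 arrays, by group. K562 replicate 1 has the lowest median of all probe sets, 2.07, and the 4 FEPS arrays lie below the other 6 in the poly-A controls.

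Lucena 1 without vincristine was compared with K562 to ask how the vincristine-selected line differed from the drug-sensitive line it came from. ABCB1, which encodes the drug efflux pump P-glycoprotein, had the largest rise of the 19741 genes tested. Its mean log2 signal was 9.85 in Lucena 1 and 2.16 in K562, a difference of 7.69 ± 0.20 (adjusted p = 2.6e-07) and at least 59.7-fold. ABCG2, a second efflux pump, rose by 3.53 ± 0.29 (adjusted p = 0.000131), at least 4.12-fold. These were the 2 members past the test among the 13 measured of the efflux transporter list. That list also holds MVP, which is not a transporter gene, and it was not called as a whole (camera adjusted p = 0.0564). ABCC1, a further drug exporter, had -0.02 ± 0.20 (adjusted p = 0.973), and the vault protein gene MVP had 0.11 ± 0.27 (adjusted p = 0.867). The topoisomerase II genes TOP2A and TOP2B, with -0.25 ± 0.30 and -0.49 ± 0.28, did not pass either (adjusted p = 0.704 and 0.358).

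Besides ABCB1, the largest fitted rises in Lucena 1 were MUC19 (7.21, at least 52.9-fold), the fatty acid transporter CD36 (6.35 ± 0.24, at least 29.4-fold), PERP (5.26), PLCL1 (5.24, at least 15.7-fold), SESN3 (5.07, at least 22.9-fold), the actin-associated gene PALLD (5.04, at least 14.5-fold) and the gap junction gene GJA1 (4.98 ± 0.27, at least 10.9-fold). The largest fitted falls were DOCK8 (-6.63 ± 0.27, at least 23.8-fold lower), the vesicle fusion gene VAMP8 (-6.19 ± 0.35, at least 61.4-fold lower), TRDV3 (-6.06, at least 21.3-fold), TRDN (-5.97, at least 17.5-fold), the interleukin-1 receptor IL1R1 (-5.50, at least 20.6-fold), the integrin ITGAM (-5.46), mitochondrial ND6 (-5.24) and desmosomal DSP (-5.20, at least 11.7-fold). On probe sets without the suffixes that mark shared sequence, PERP (0.11), PALLD (0.17), TRDV3 (0.008) and ITGAM (-0.20) were not called.

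Of the 13 measured genes that flank ABCB1 on chromosome 7, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 difference of 0.62 and camera adjusted p = 0.00024 (adjusted p = 0.325 with an estimated correlation). The calcium-binding gene SRI rose by 2.41 ± 0.21, ELAPOR2 by 1.93 ± 0.24, ADAM22 by 1.60 ± 0.21, the replication kinase subunit DBF4 by 1.20 ± 0.28 and TMEM243 by 1.19 ± 0.21. ADAM22 had 1.08 on probe sets without shared-sequence suffixes and was not called (adjusted p = 0.105). SLC25A40, with 1.06 ± 0.29, fell short of the test (adjusted p = 0.0564), as did DMTF1 with 0.62 ± 0.27 (adjusted p = 0.23). The plot of the flanking genes gives them in their order along the chromosome.

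Among 15 histone genes 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.27, camera adjusted p = 5.04e-07 and adjusted p = 0.153 with an estimated correlation. H2BC11 rose by 2.88 (at least 4.78-fold), H2BC6 by 2.22, H2BC9 by 1.68 and H2AC8 by 1.66. In the unfolded protein and amino acid response, 7 rose and 1 fell of 29 genes (9 and 1 adjusted over the list alone), with a median of 0.59, camera adjusted p = 7.11e-06 and adjusted p = 0.153 with an estimated correlation. Its largest rises were the stress transcription factor ATF3 (2.17 ± 0.22), PPP1R15A (2.02), asparagine synthetase ASNS (1.46) and CEBPG (1.29). Glycolysis and hypoxia-response genes counted 32, of which 5 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.57, camera adjusted p = 8.3e-05 and adjusted p = 0.222 with an estimated correlation. They included ANKRD37 (2.17 ± 0.21), the glucose transporter SLC2A3 (1.59), enolase ENO2 (1.23) and the oxygen-sensing hydroxylase EGLN3 (1.06). For cholesterol synthesis 2 rose and 0 fell of 19 (4 and 0 adjusted over the list alone), namely MSMO1 (1.48) and SQLE (0.82), with a median of 0.50, camera adjusted p = 0.0497 and adjusted p = 0.548 with an estimated correlation. Of 34 adhesion and mesenchymal genes 5 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.48, camera adjusted p = 0.00768 and adjusted p = 0.499 with an estimated correlation. The median was 0.17 when group means under background were set to it. S100A10 rose by 2.19, while ICAM1 fell by 2.35 and SPARC by 2.21. Of the genes named here ATF3 (1.18), ASNS (0.34), SQLE (0.82) and SPARC (-0.81) were not called on probe sets without shared-sequence suffixes. The adhesion list was no longer called by camera without K562 replicate 2 (adjusted p = 0.15), on probe sets without those suffixes (0.225) or with the filter on mean signal (0.0828). Cholesterol synthesis was not called without K562 replicate 2 (adjusted p = 0.25), Lucena 1 without drug replicate 1 or 2 (0.0852 and 0.062) or FEPS with drug replicate 1 or 2 (0.0576 and 0.0591). Its call also ended with the filters on the mean (0.122) and the highest group mean (0.109), without suffixes (0.0712), in a fit of these groups alone (0.0536), and with a replicate block for all arrays (0.0531) or for K562 and Lucena 1 (0.0629).

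The other 20 lists had camera adjusted p from 0.0564 to 0.975. Within the BCR-ABL, STAT5 and ERK target list, 5 rose and 2 fell of 30, among them the signalling suppressor SOCS3 (3.06), PHLDA1 (2.96) and FOS (2.40, at least 4.4-fold) upward and ID1 (-1.72) downward. Of 37 interferon-stimulated genes 2 rose and 5 fell, among them HERC6 (2.43, at least 1.68-fold) and ISG15 (2.05) upward and SAMD9 (-2.78, at least 3.39-fold) and CMPK2 (-2.15) downward. Of 29 tubulin and microtubule genes 2 rose and 0 fell, the tubulins TUBA4A (2.07) and TUBB2B (1.61). For 26 erythroid genes 2 rose and 2 fell (camera adjusted p = 0.975), with HEMGN at 3.26 and the delta-globin HBD at -1.29. Of 34 lysosome genes 2 rose and 3 fell, among them the protease CTSS (-3.16) and the cholesterol exporter NPC1 (1.66).

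In all, 1480 genes passed the limma test between Lucena 1 and K562, of which 754 were higher and 726 lower in Lucena 1, and 1334 differed by at least 2-fold. At an unadjusted p under 0.05 there were 4225, where chance gives 987. The groups did not overlap for 47.4% of genes, against 33.3% by chance. As deposited, 2394 genes passed and 96.9% of them were higher in Lucena 1, against 50.9% after normalization, with an all-gene median shift of 1.16. The count was 503 without Lucena 1 without drug replicate 1, 701 without its replicate 2, 633 without K562 replicate 2 and 744 when the spread came from these groups alone, against 2543 with a replicate block for K562 and Lucena 1 and 2706 with a covariate for RNA integrity.

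FEPS without daunorubicin was compared with K562 to ask the same of the daunorubicin-selected line. ABCB1 again had the largest rise, from 2.16 in K562 to 12.15 in FEPS, a difference of 9.99 ± 0.20 (adjusted p = 2.27e-08) and at least 294-fold. ABCB4, a phospholipid transporter next to ABCB1, rose by 2.54 ± 0.45 (adjusted p = 0.00512), at least 4.53-fold, and MVP was lower by at least 2.36-fold (adjusted p = 0.00459). In the efflux transporter list of 13 measured genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), MVP being the fall. The list was not called (camera adjusted p = 0.175). ABCG2 (1.19) and ABCB11 (1.33, at least 1.88-fold) were the other rises, and the ABCG2 signal was under background in both groups. Neither ABCB4 (0.50) nor ABCB11 (0.27) was called on probe sets without shared-sequence suffixes. Neither ABCC1 (0.08 ± 0.20, adjusted p = 0.831) nor TOP2A (-0.22 ± 0.30, adjusted p = 0.653) nor TOP2B (-0.70 ± 0.28, adjusted p = 0.115) passed the test.

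The other large rises in FEPS were the actin-severing gene SCIN (8.06 ± 0.27, at least 72.5-fold), NT5DC4 (7.34, at least 47.6-fold), FCER1A (6.77, at least 35.7-fold), CNRIP1 (6.40, at least 42-fold), GJA1 (5.93, at least 21.1-fold), the Notch target HEY1 (5.92) and CD36 (5.88, at least 21.1-fold). The proteoglycan gene SRGN fell by 8.71 ± 0.28 (adjusted p = 2.88e-07), at least 97.2-fold. LINC01419 (-8.54, at least 78.8-fold), the leukotriene enzyme ALOX5 (-7.85, at least 76.7-fold), WDR72 (-7.59, at least 62.9-fold), CILP (-7.57), TMEM132D-AS1 (-7.56, at least 173-fold), ITGAM (-7.37, at least 74.6-fold) and VAMP8 (-7.28, at least 61.4-fold) also fell. On probe sets without shared-sequence suffixes FCER1A (0.165) and ITGAM (0.78) were not called.

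Among genes flanking ABCB1, 6 rose and 0 fell of 13 (6 and 0 adjusted over the list alone), with a median of 0.70, or 0.32 with background set as the floor, camera adjusted p = 0.0113 and adjusted p = 0.274 with an estimated correlation. The list was not called on probe sets without shared-sequence suffixes (camera adjusted p = 0.0826). Those that rose were ABCB4, TMEM243 (2.40 ± 0.21), DMTF1 (2.08 ± 0.27), ELAPOR2 (1.81 ± 0.24), DBF4 (1.48 ± 0.28) and SRI (1.34 ± 0.21). SLC25A40, with -0.29 ± 0.29, and ADAM22, with 0.32 ± 0.21, did not pass (adjusted p = 0.529 and 0.322).

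**Figure D2:**
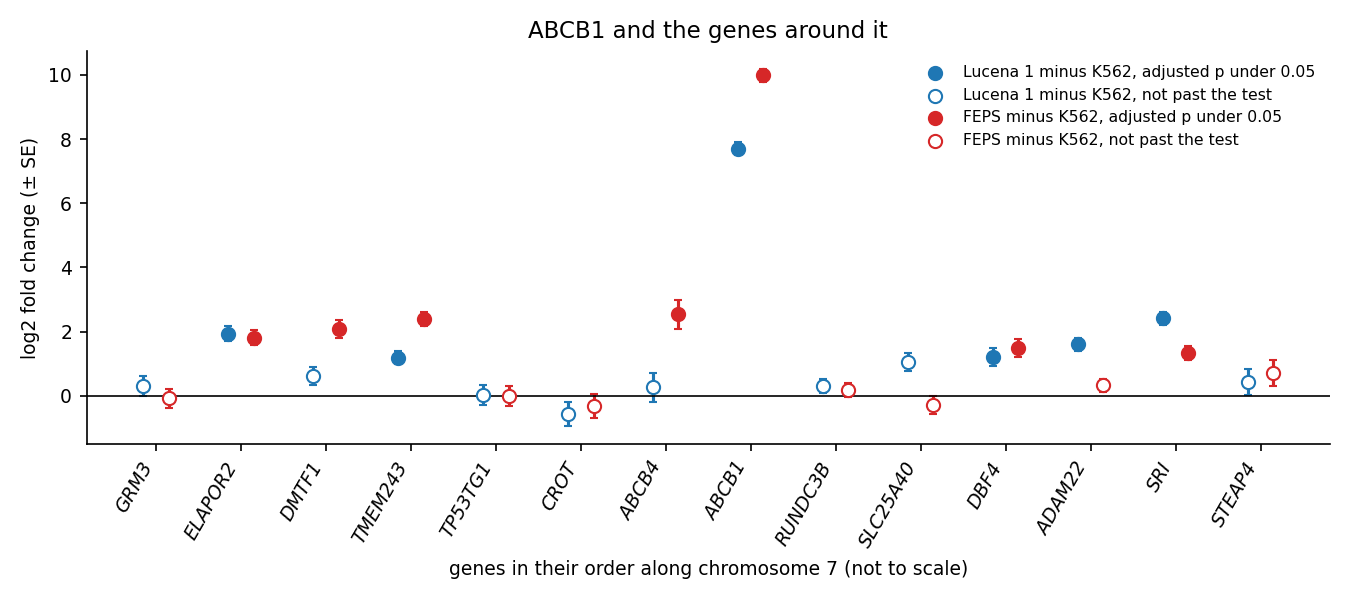
Log2 difference from K562 (± SE) of ABCB1 and its 13 flanking genes in Lucena 1 and FEPS without drug, in gene order along chromosome 7 and not to scale, with filled points at adjusted p under 0.05. ABCB1 stands at 7.69 and 9.99, and the flanking genes past the test lie between 1.19 and 2.54.

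Erythroid genes included 26 measured members, of which 11 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.78, camera adjusted p = 0.000588 and adjusted p = 0.269 with an estimated correlation. The adult and embryonic globins HBB (5.76 ± 0.22) and HBE1 (4.16 ± 0.27) and HEMGN (2.75) rose. Of 37 DNA replication genes 12 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.64, camera adjusted p = 1.63e-05 and adjusted p = 0.269 with an estimated correlation. MCM7 (2.08) and MCM5 (1.93), which belong to the replicative helicase, and thymidine kinase TK1 (2.05) were examples. In cholesterol synthesis 6 rose and 1 fell of 19, with a median of 0.58, camera adjusted p = 0.0274 and adjusted p = 0.369 with an estimated correlation, among them PMVK (1.92), LSS (1.83), NSDHL (1.67) and FDPS (1.36). For histones 6 rose and 1 fell of 15, with a median of 0.46, or 0.72 with the covariate for RNA integrity, camera adjusted p = 0.0189 and adjusted p = 0.274 with an estimated correlation, including H2BC6 (2.81), H2BC9 (2.08) and H2BC11 (2.03, at least 2.64-fold). HBB had 0.74 on probe sets without shared-sequence suffixes and was not called. Histones were not called without K562 replicate 1 (camera adjusted p = 0.0609), nor cholesterol synthesis without K562 replicate 2 (0.0815) or FEPS without drug replicate 1 (0.0632). The poly-A controls differed along with these groups, by 2.69 between the lowest normalized median of the other arrays and the highest of FEPS.

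Glycolysis and hypoxia-response genes went the other way, with 32 measured, of which 2 rose and 7 fell, a median of -0.38, camera adjusted p = 0.00526 and adjusted p = 0.269 with an estimated correlation. SLC2A3 (-2.88 ± 0.28), the hypoxia-induced repressor BHLHE40 (-2.71 ± 0.22) and phosphofructokinase PFKM (-2.18) fell, and ADM (1.85, at least 2.59-fold) rose. Of 37 interferon-stimulated genes 1 rose and 9 fell (2 and 9 adjusted over the list alone), with camera adjusted p = 0.0113 and adjusted p = 0.269 with an estimated correlation. BST2 (-3.87), IFITM3 (-3.31), IFITM1 (-2.67) and OAS3 (-2.41, at least 4.64-fold) fell. Their list median was -0.18, or 0 with background set as the floor, since 15 of the 37 lay under it in both groups. Of 37 apoptosis genes 4 rose and 7 fell (4 and 10 adjusted over the list alone), with a median of -0.23, or -0.37 with the covariate for RNA integrity, camera adjusted p = 0.013 and adjusted p = 0.27 with an estimated correlation, the death ligand TNFSF10 (-3.26, at least 3.06-fold) and CASP4 (-1.83) among the falls. The 34 adhesion and mesenchymal genes, of which 2 rose and 9 fell (2 and 10 adjusted over the list alone), were called downward (camera adjusted p = 0.0489, adjusted p = 0.466 with an estimated correlation) on a mean of -0.43, while their median was 0.0005. ANXA1 (-6.12 ± 0.23, at least 54.4-fold lower) and the matrix gene SPARC (-4.90, at least 8.88-fold) fell. For ribosomal proteins 0 rose and 2 fell of 33 (0 and 0 adjusted over the list alone), with a median of -0.13, camera adjusted p = 0.0189 and adjusted p = 0.312 with an estimated correlation. Both, RPL3 and RPS7, were higher as deposited (0.53 and 0.77), where the median of all genes shifted by 1.64. CASP4 had -0.27 on probe sets without shared-sequence suffixes and was not called. Some of these list calls ended in camera when 1 array was left out: apoptosis without K562 replicate 1 (adjusted p = 0.143), ribosomal proteins without K562 replicate 2 (0.0696; 0.0713 without those suffixes), and adhesion without K562 replicate 1 (0.222), FEPS without drug replicate 1 (0.0632) or any array with drug (0.0603 to 0.0759). The adhesion call also ended with centred arrays (0.0856), the mean of probe sets (0.16), probe sets without those suffixes (0.0907), a fit of these groups alone (0.104) and a replicate block (0.0556). Glycolysis was not called as deposited (0.0683) or with centred arrays (0.0531). As in the groups that rose, the gap of 2.69 in the poly-A controls ran with these falls.

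The other 16 lists had camera adjusted p from 0.061 to 0.912. The ER stress list, with 29 genes of which 2 rose and 5 fell, had a median of 0.06 and a mean of -0.12, and DDIT3 fell by 2.06. Of 22 p53 targets 2 rose and 4 fell, with TP53INP1 (-4.30) and the death receptor TNFRSF10B (-2.90) lower. For 39 glutathione and detoxification genes 8 rose and 6 fell, including CBR1 (2.25), which reduces anthracyclines, and glutathione reductase GSR (2.08) upward and ALDH1A1 (-4.50, at least 6.17-fold) and GSTT1 (-1.98) downward. Of 29 tubulin and microtubule genes 5 rose and 2 fell, TUBB6 at 1.97 and MAP7 at -1.78. Among 30 BCR-ABL, STAT5 and ERK targets 6 rose and 8 fell, with the STAT5 targets CISH (-2.89) and SOCS3 (-2.75, at least 2.23-fold) lower and FOS (2.66, at least 5.25-fold) higher. Of 20 heat shock genes 7 rose and 1 fell, DNAJB1 (1.26) and HSPH1 (1.12, or 0.28 and not called on probe sets without shared-sequence suffixes) among the rises.

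In FEPS 3573 genes passed the limma test against K562, 1904 higher and 1669 lower, and 2863 of them differed by at least 2-fold. At an unadjusted p under 0.05 there were 6358, where chance gives 987. Groups did not overlap for 61.2% of genes, against 33.3% by chance. As deposited, 12008 genes passed and 98.1% were higher in FEPS, against 53.3% after normalization and 34.8% with arrays centred on their medians, with an all-gene shift as deposited of 1.64. The count was 1428 without FEPS without drug replicate 1, 1584 without its replicate 2 and 1951 without K562 replicate 2.

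**Figure D3:**
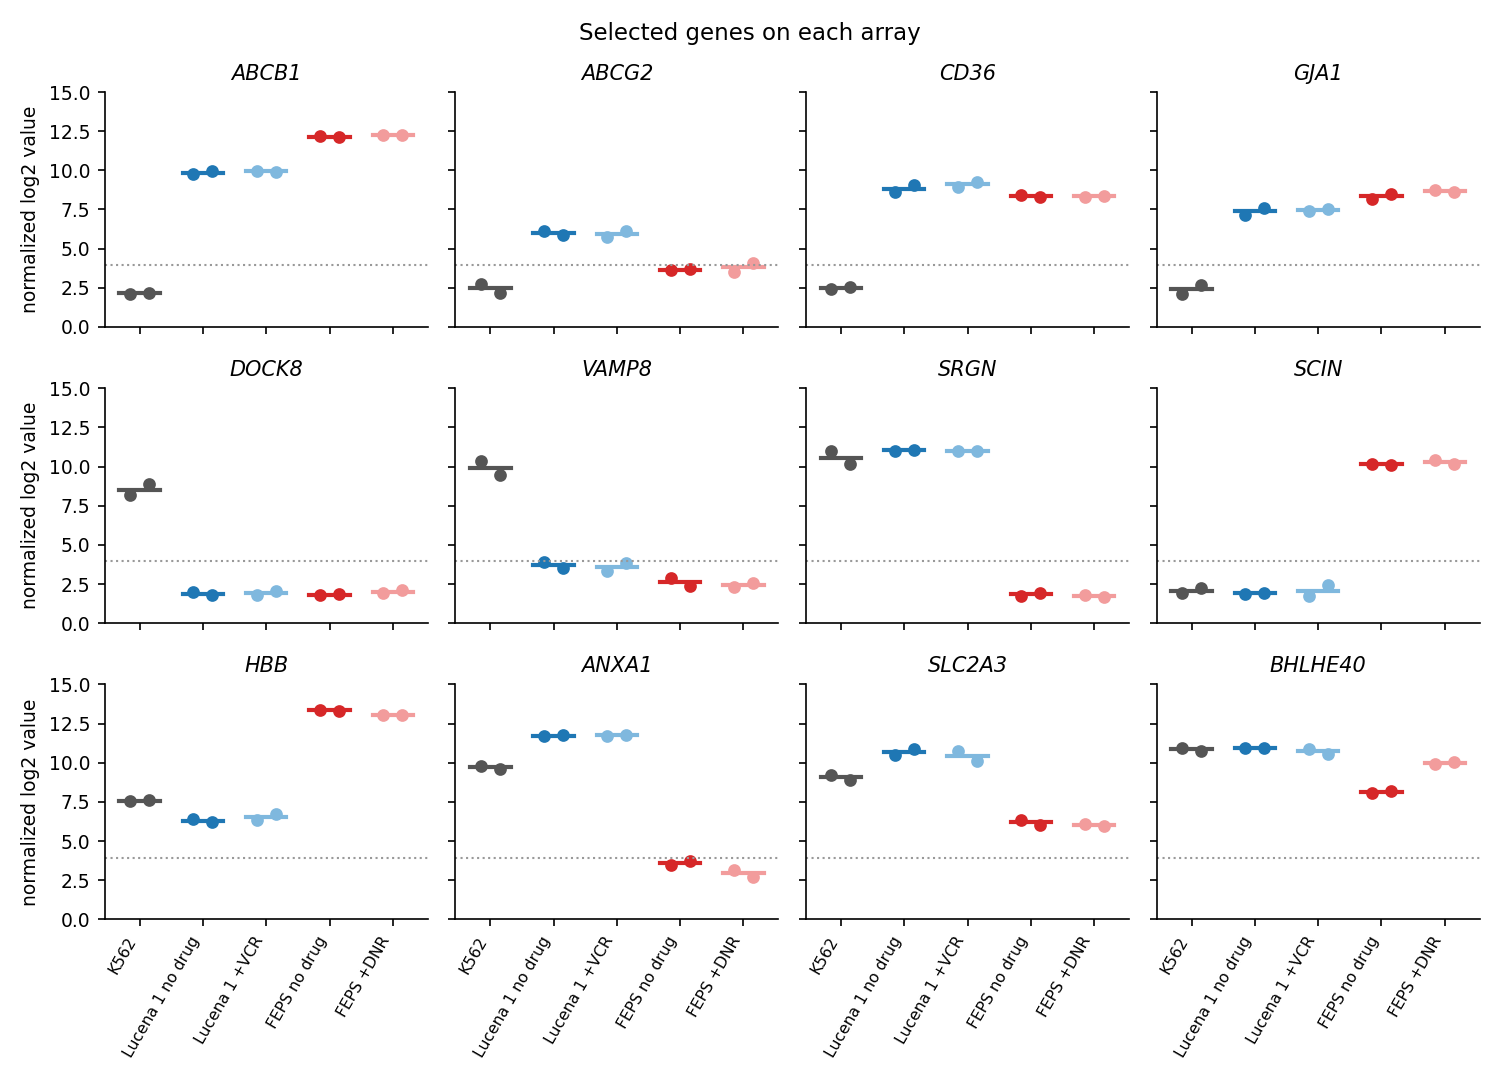
Normalized signal (log2) of 12 named genes on each of the 10 arrays by group, with a bar at each group mean and a dotted line at 3.95, the median of all probe sets. ABCB1 lies near 10 in Lucena 1 and 12 in FEPS with or without drug, and below the dotted line in K562.

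Both resistant lines shared 678 called changes of the same direction against K562, 283 rises and 395 falls. Independent lists of these sizes would share 72.7 rises and 61.4 falls. Ranked by the smaller of both changes, the shared rises were led by ABCB1, CD36 and GJA1, followed by JPH1 (4.21 in Lucena 1 and 4.62 in FEPS, at least 11.8-fold and 15.7-fold), MUC19 (7.21 and 4.15, at least 52.9-fold and 6.34-fold), the caveolin CAV2 (4.43 and 3.85, at least 15-fold and 10-fold), FAM171B (3.52 and 3.67, at least 2.97-fold and 3.29-fold) and JAZF1 (3.67 and 3.51, at least 9.14-fold and 8.18-fold). The leading shared falls were DOCK8 (-6.63 and -6.70, at least 23.8-fold and 23.8-fold), VAMP8 (-6.19 and -7.28, at least 61.4-fold and 61.4-fold), TRDV3, TRDN (-5.97 and -6.06, at least 17.5-fold and 17.5-fold), ITGAM, DSP (-5.20 and -5.25, at least 11.7-fold and 11.7-fold), RGS18 (-4.89 and -5.12, at least 10.2-fold and 10.2-fold) and GAS2 (-4.80 and -4.91, at least 9.07-fold and 9.07-fold). On probe sets without shared-sequence suffixes TRDV3 had 0.008 and 0.14 in the 2 lines and ITGAM -0.20 and 0.78, and neither was called. A further 85 genes were called in opposite directions. Both comparisons used the same 2 K562 arrays, and 100 simulations with no true change gave 0 shared calls but a correlation of 0.499 across genes, against 0.461 observed. With no gene changed almost no calls can arise, so the 0 is no baseline for lists of these sizes. The observed covariance of the changes was 0.298, above the 0.0548 of the simulations. The simulations took the arrays as unpaired, although same-number arrays of K562 and Lucena 1 deviated together, so 0.0548 is not a matched baseline. The 2 control arrays are too few for each comparison to be given a pair of its own, so part of the overlap may come from sharing them. The shared count was 1781 as deposited, 319 without K562 replicate 2, 282 and 347 without Lucena 1 without drug replicates 1 and 2, and 363 and 372 without FEPS without drug replicates 1 and 2.

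FEPS and Lucena 1, both without drug, were compared to ask how the resistant lines differ from each other. SCIN (8.22 ± 0.27, at least 72.5-fold) and HBB (7.04 ± 0.22, adjusted p = 2.66e-07) had the largest fitted rises in FEPS over Lucena 1, and the next were FCER1A (6.63, at least 35.7-fold), the thrombin receptor family gene F2RL2 (6.13, at least 16.3-fold), LGALS8 (6.08, at least 30.5-fold), NT5DC4 (6.06, at least 47.6-fold), PKIB (4.90, at least 13.8-fold) and SLITRK4 (4.75, at least 6.95-fold). On probe sets without shared-sequence suffixes HBB (0.45), FCER1A (-0.17), ABCB4 (0.59) and SRI (-0.67) were not called. SRGN was lower in FEPS by at least 135-fold (-9.19 ± 0.28, at least 135-fold) and ANXA1, an inflammation regulator, by at least 219.6-fold (-8.13 ± 0.23, at least 219.6-fold). LINC01419 (-8.39, at least 71.1-fold), the growth factor EREG (-7.77, at least 49.4-fold), TEX19 (-7.59), TMEM132D-AS1 (-7.55, at least 172-fold), WDR72 (-7.02, at least 42.2-fold) and FGF13 (-6.74, at least 39.1-fold) followed. ABCB1 was higher in FEPS by 2.30 ± 0.20 (adjusted p = 0.000106) and ABCB4 by 2.28 ± 0.45, while ABCG2 was lower by at least 4.12-fold (-2.34 ± 0.29, adjusted p = 0.000741). ABCC5 was higher at 0.83 and MVP lower by at least 2.55-fold. Of 13 genes flanking ABCB1, 3 rose and 3 fell (camera adjusted p = 0.94): DMTF1 (1.46) and TMEM243 (1.21) were higher with ABCB4, and SLC25A40 (-1.35), ADAM22 (-1.28) and SRI (-1.07) were lower.

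Genes of glycolysis and the hypoxia response were lower in FEPS than in Lucena 1: of 32, 2 rose and 15 fell (3 and 17 adjusted over the list alone), with a median of -0.88, camera adjusted p = 1.87e-08 and adjusted p = 0.0628 with an estimated correlation. SLC2A3 (-4.47 ± 0.28), ANKRD37 (-2.79 ± 0.21), BHLHE40 (-2.77) and PFKM (-2.59) fell. ER stress and amino acid response genes were lower too: of 29, 0 rose and 11 fell (0 and 15 adjusted over the list alone), with a median of -0.64, or -0.99 with the covariate for RNA integrity, camera adjusted p = 3.85e-07 and adjusted p = 0.0628 with an estimated correlation. They included DDIT3 (-2.99 ± 0.39), PPP1R15A (-2.23) and the chaperone HSPA5 (-2.19 ± 0.21). DNA replication genes were higher in FEPS, where 13 rose and 0 fell of 37 (19 and 0 adjusted over the list alone), with a median of 0.68, camera adjusted p = 3.85e-07 and adjusted p = 0.0628 with an estimated correlation. MCM7 (1.84), cyclin CCNE2 (1.78), POLA1 (1.59) and GINS1 (1.44) were examples. Of 26 erythroid genes 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.61, or 0.33 with the covariate for RNA integrity, camera adjusted p = 0.00224 and adjusted p = 0.269 with an estimated correlation, HBD at 3.87 and HBE1 at 3.57. The same 2.69 gap in the poly-A controls parts FEPS from Lucena 1 in all of these groups and in those that follow.

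Of 34 adhesion and mesenchymal genes 1 rose and 12 fell (1 and 13 adjusted over the list alone), with a median of -0.46, or -0.07 with background set as the floor and -0.83 with the covariate for RNA integrity, camera adjusted p = 3.89e-05 and adjusted p = 0.269 with an estimated correlation. Galectin LGALS1 (-3.14), S100A10 (-3.09) and SPARC (-2.69, at least 1.92-fold) fell. Of 22 p53 targets 1 rose and 4 fell, with a median of -0.64, camera adjusted p = 0.0177 and adjusted p = 0.163 with an estimated correlation, TNFRSF10B (-3.63) and GADD45A (-1.56) among the falls. In the apoptosis list 1 rose and 6 fell of 37, with a median of -0.33, or -0.19 with background set as the floor, camera adjusted p = 0.0209 and adjusted p = 0.315 with an estimated correlation, and the falls included the pro-apoptotic HRK (-2.55, at least 4.31-fold) and BCL2L11 (-2.19). Of 37 interferon-stimulated genes 3 rose and 10 fell (4 and 12 adjusted over the list alone), with a median of -0.34, or 0 with background set as the floor, camera adjusted p = 0.0499 and adjusted p = 0.299 with an estimated correlation. SAMD9 (3.95, at least 7.59-fold) was higher, and BST2 (-3.49), IFITM3 (-2.87) and IFITM1 (-2.82) were lower. SPARC (-0.37), HRK (-0.64) and BCL2L11 (-0.78) were not called on probe sets without shared-sequence suffixes. Camera no longer called p53 targets without Lucena 1 without drug replicate 2 (adjusted p = 0.0632), with the mean of probe sets (0.0648) or with the covariate for RNA integrity (0.0546). The apoptosis call ended without that array (0.0554), with the filters on the mean (0.113) and the highest group mean (0.073), with the mean of probe sets (0.0648) and without shared-sequence suffixes (0.294). Interferon-stimulated genes were not called without that array (0.106), K562 replicate 1 (0.0599) or 2 (0.0577), or FEPS without drug replicate 2 (0.0737). Nor were they with the filter on the mean (0.176), as deposited (0.0717), with centred arrays (0.106), in a fit of these groups alone (0.0674), with a replicate block for all arrays (0.0568) or for K562 and Lucena 1 (0.0995), or with the covariate (0.102). The other 18 lists had camera adjusted p from 0.0506 to 0.991, and within them SOCS3 (-5.80, at least 18.6-fold), CISH (-3.23) and SOCS1 (-2.76) were lower and CBR1 (2.69) and NQO1 (1.61) higher in FEPS.

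Between FEPS and Lucena 1, 2943 genes passed the limma test, 1383 higher and 1560 lower in FEPS, and 2442 differed by at least 2-fold. At an unadjusted p under 0.05 there were 5520, where chance gives 987. Groups did not overlap for 59.2% of genes, against 33.3% by chance. As deposited 639 genes passed, and with arrays centred on their medians 29.9% of called genes were higher in FEPS, against 47% after quantile normalization. The count was 1324 and 1394 without FEPS without drug replicates 1 and 2, and 1563 and 1623 without Lucena 1 without drug replicates 1 and 2.

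**Figure D4:**
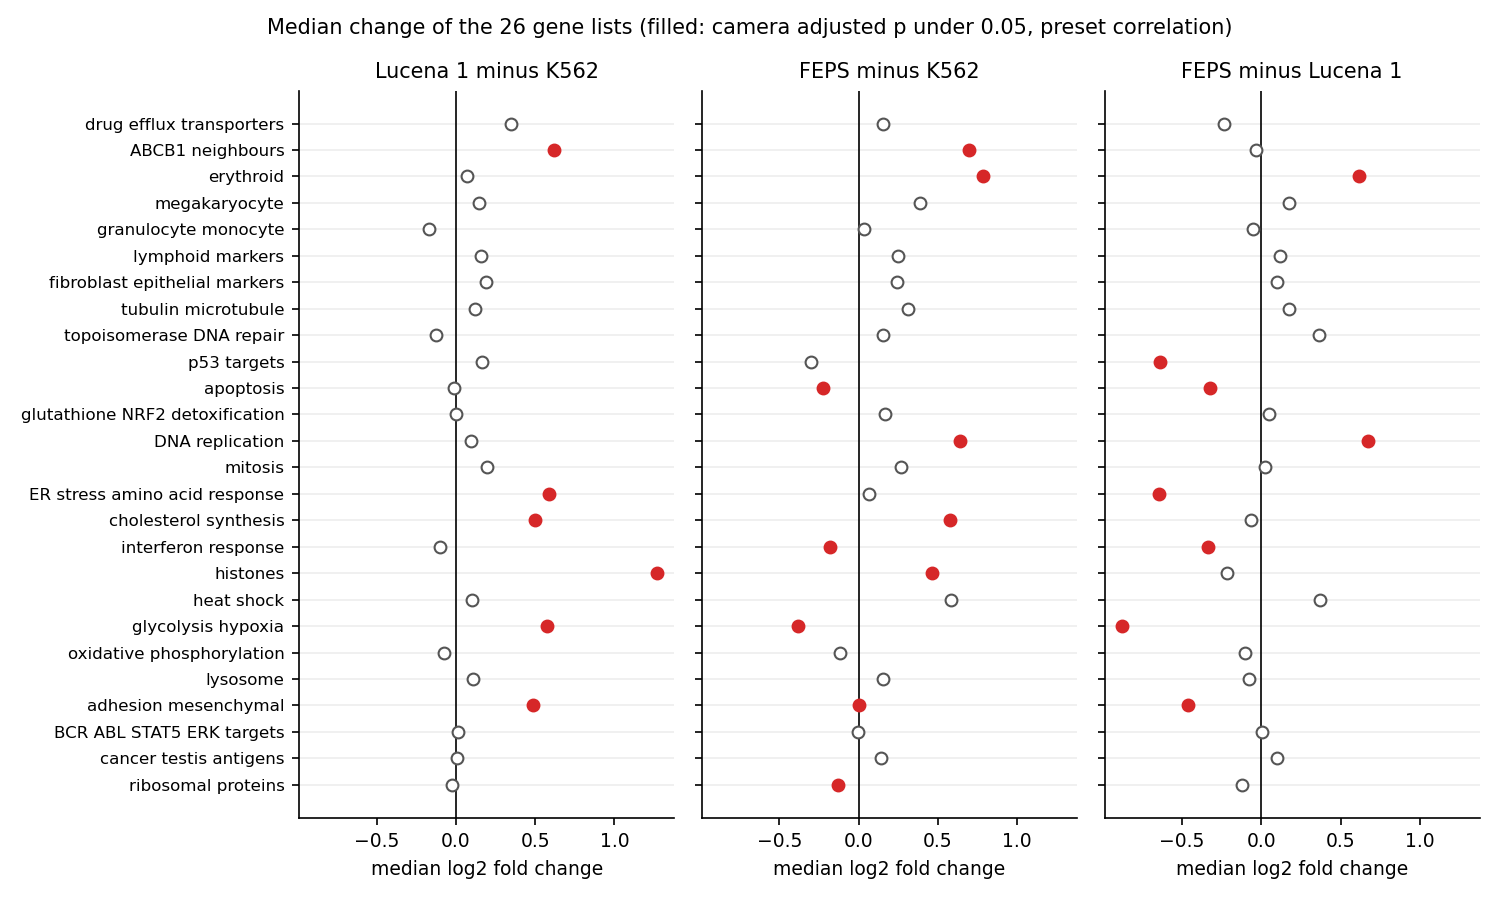
Median log2 difference of the 26 gene lists in the 3 comparisons between lines, with filled points at camera adjusted p under 0.05 for the preset correlation of 0.01. Glycolysis and hypoxia-response genes stand at 0.57 in Lucena 1 and -0.38 in FEPS, both against K562.

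The 2 drug comparisons asked what continued exposure adds in each resistant line. ABCB1 was at 9.95 with vincristine and 9.85 without it in Lucena 1, a difference of 0.10 ± 0.20, and at 12.25 with daunorubicin and 12.15 without it in FEPS, a difference of 0.10 ± 0.20. Neither difference passed the test (adjusted p = 1 and 0.947). In Lucena 1 no gene passed: limma gave 0 genes at adjusted p under 0.05, with 476 at an unadjusted p under 0.05 where chance gives 987. Groups did not overlap for 24.4% of genes, against 33.3% by chance. No list was called in the main setting (smallest camera adjusted p = 0.145), against 3 as deposited, 3 with centred arrays and 2 with the covariate for RNA integrity. ABCG2 (-0.06 ± 0.29), ABCC1 (-0.08 ± 0.20), MVP (-0.20 ± 0.27), TOP2A (0.04 ± 0.30) and TOP2B (-0.15 ± 0.28) had adjusted p = 1. Simulated data with these arrays' spread and 200 changed genes had 91% of changes of 2 and 17.9% of changes of 1 on the log2 scale recovered. With fewer true changes the adjusted threshold is stricter, so a smaller share would be recovered. That simulation, the chance count and the chance share all take the arrays as unpaired, although same-number arrays of both Lucena 1 groups deviated together.

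In FEPS 5 genes differed with daunorubicin, 1 higher and 4 lower, with 1649 at an unadjusted p under 0.05 where chance gives 987. Groups did not overlap for 45% of genes, against 33.3% by chance. BHLHE40, a hypoxia and stress-induced repressor, rose by 1.85 ± 0.22 (adjusted p = 0.046). The centrosomal gene CEP112 was lower by at least 5.23-fold (-3.86 ± 0.38, adjusted p = 0.0237), UBE2U by at least 3.03-fold (-3.35 ± 0.25, adjusted p = 0.00446), and PTTG3P (-2.40 ± 0.26, adjusted p = 0.0385) and the replication fork helicase SMARCAL1 (-1.83 ± 0.22, adjusted p = 0.046) were lower too. TOP2A had 0.25 ± 0.30 (adjusted p = 0.885). Of 20 heat shock genes none passed singly, and the list was called downward (median -0.29, camera adjusted p = 0.0127, adjusted p = 0.348 with an estimated correlation). The 26 erythroid genes were called upward (median 0.25, camera adjusted p = 0.0127, adjusted p = 0.787 with an estimated correlation), with 1 and 0 past the test adjusted over the list alone. Neither list was called without FEPS with drug replicate 1 (camera adjusted p = 0.132 for both). The erythroid call ended without FEPS without drug replicate 1 (0.0677), and that of heat shock without its replicate 2 (0.0708), on probe sets without shared-sequence suffixes (0.0732), as deposited (0.135) and with centred arrays (0.101). The count of 5 became 86 as deposited, where 1.2% of called genes were higher with drug against 20% after normalization. It was 17 with arrays centred on their medians, 12 with an intensity trend, 11 with the mean of a gene's probe sets, and 0 with a filter on mean signal or a fit of these groups alone. With a replicate block it was 2, with 0 higher and 2 lower, so BHLHE40 was not called. With the block for K562 and Lucena 1 only it was 8. It was 38 without FEPS with drug replicate 1, from 1 to 2 without an array of K562 or Lucena 1, and 0 without any other FEPS array.

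Whether the change with drug differed between the lines was tested as an interaction, in which line and drug cannot be told apart. In limma 0 genes passed, with 997 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0741, and no list was called (smallest camera adjusted p = 0.0754). Without FEPS with drug replicate 1 there were 9 genes, and the other alternatives that moved the count gave from 1 to 3.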

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

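Among the tests in this part, those of the separate preparation of the FEPS arrays, of the flanking genes with background as the floor and of the flanking window of genes expressed in K562 were chosen after the result was seen, as was the reason for leaving the window of measured genes undecided.

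Of 13 genes that flank ABCB1, 5 rose with it in Lucena 1 and 6 in FEPS, with list medians of 0.62 and 0.70, or 0.62 and 0.32 with background set as the floor, and the list was not called with an estimated correlation (adjusted p = 0.325 and 0.274) nor, in FEPS, on probe sets without shared-sequence suffixes (adjusted p = 0.0826). A bias with signal level is argued against, since both medians lay at or above percentile 99.78 of 10000 random lists of matched signal, and at or above percentile 99.29 with the floor applied to all. A regional change, the biological candidate, stays open: by the criterion written beforehand, the median of the window of 10 measured genes around ABCB1 (0.84 in Lucena 1 and 0.83 in FEPS) had to exceed the highest window in at least 95 of 100 shuffles of gene order, and it exceeded 14 and 0. Of those 10, 4 (TP53TG1, CROT, ABCB4 and RUNDC3B) were under background in K562, where only a rise past background can be seen, and a window of 10 genes chosen for expression in K562 alone (1.40 and 1.65) exceeded 100 and 100 shuffles. Against a change of the whole region, SEMA3A in that window was called lower in FEPS (adjusted p = 2.82e-05) and SLC25A40 and ADAM22 were not called there, copy number was not measured, and a regional change may or may not underlie these rises.

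More genes differed from K562 in FEPS, 3573, than in Lucena 1, 1480, and no test of that difference between counts was made. Same-number arrays of K562 and Lucena 1 deviated together, but not those of FEPS. With a replicate block for K562 and Lucena 1 only, added after the data were seen, the counts were 3815 and 2543. K562 replicate 1, which both comparisons share, was dim and stayed low in the hybridization controls after normalization (7.63, against 8.63 or more on the other arrays). The dim array K562 replicate 1 is argued against as the cause, since without it the FEPS count (2902) was still 2.44 times the Lucena 1 count (1189). Separate preparation of the FEPS arrays, which no label states and which is inferred from the control signal alone, cannot be told apart from the line, because all 4 FEPS arrays lay at least 2.691 below the other 6 in the poly-A controls. RNA integrity stays open as well, since with the ACTB covariate the counts were 3365 and 2706, a ratio of 1.244 that falls between the bounds set for either reading. The GAPDH 3′ minus 5′ difference, which was not used as a covariate, did not part the lines (0.1 to 0.28 on the FEPS arrays and 0.04 to 0.35 on the others). A larger divergence of FEPS from K562, the biological candidate, was not tested apart from these.

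Genes of the ER stress and amino acid response and of glycolysis and hypoxia were higher in Lucena 1 than in K562 and lower in FEPS than in Lucena 1, and the glycolysis list was also lower in FEPS than in K562, but with an estimated correlation none of these lists was called (adjusted p = 0.153 and 0.222 in Lucena 1, 0.0628 for both between the lines and 0.269 in FEPS), and the members risen in Lucena 1 were 7 of 29 and 5 of 32. With the ACTB covariate at least 123.3% of each list's median difference between the lines was kept. RNA integrity stays open even so, since the covariate's slope comes from differences within groups. Those ran with replicate number in K562 and Lucena 1 and were small in FEPS, so integrity and replicate cannot be told apart. At least 79.2% was kept when any 1 chromosome was left out. The members of both lists are spread over many chromosomes, so leaving out the few on 1 of them can hardly move a list median. That test therefore decides nothing about a block of genes on 1 chromosome, and blocks on several could not be tested in this way either. For the rise in Lucena 1, with list medians of at least 0.573, the preparation of the FEPS arrays is argued against, since no FEPS array is in the groups compared. FEPS arrays do share the normalization, the estimate of spread and the choice of probe set per gene. As deposited, where FEPS values enter the list medians only through that choice, these were 0.79 for ER stress and 0.71 for glycolysis relative to all genes. For the lower values in FEPS than in Lucena 1, with list medians of -0.644 for ER stress and -0.882 for glycolysis and hypoxia, preparation and line cannot be told apart. Against K562 the ER stress list was not called in FEPS (median 0.06, camera adjusted p = 0.245), so for it the difference goes mostly with the rise in Lucena 1. Different states of the lines in culture may lie behind the lists, but cell density and medium age at harvest are not given in the sources used here and no biological explanation was tested.

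The following genes were called against K562 in both lines and in opposite directions, and each value is the fitted log2 difference of FEPS minus Lucena 1. Lower in FEPS and higher in Lucena 1 were ANXA1 (-8.131), the growth factor EREG (-7.769), TEX19 (-7.593), SOCS3 (-5.804), SLC2A3 (-4.47), LGALS1 (-3.137), S100A10 (-3.086), the histone H2BC21 (-2.289) and HSPA5 (-2.192). Higher in FEPS and lower in Lucena 1 were HBB (7.041), LGALS8 (6.08), HBD (3.875) and the lysosomal membrane gene LAMP1 (1.86). For 4 of them 1 of the 2 groups was under background and only a bound holds: at least 220-fold for ANXA1, 49.4-fold for EREG, 18.6-fold for SOCS3 and 30.5-fold for LGALS8. The fall of HBB in Lucena 1 became a difference of 0.285 on probe sets without shared-sequence suffixes, where that between the lines was 0.454 and not called. The list of adhesion and mesenchymal genes, called upward in Lucena 1 and downward in FEPS, had a median difference of -0.464, or -0.07 with background set as the floor. Its median in FEPS against K562 was 0.0005, and neither call held with an estimated correlation (adjusted p = 0.499 and 0.466).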

How the results depend on the processing

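The replicate block for K562 and Lucena 1 only and the ACTB covariate were chosen after the data were seen, and all other alternatives given in this part were written down before; quantile normalization, one of them, replaced the values as deposited as the main setting before any test. Over all alternatives the 305 named gene results kept direction and call 5731 times, lost the call with the same direction 614 times and reversed 29 times. Genes with only suffixed probe sets had unchanged values in the setting without suffixes, so results kept there are no check for them. The 26 called list results were kept 510 times, lost 88 times and never reversed. ABCB1 is not among the reversed genes. Values under 3.95 were treated as background, and small changes were recovered seldom in simulated data. For every change below the cause was not tested, unless it is stated.

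As deposited, 2394 genes were called in Lucena 1 against K562 (1480 in the main setting), 12008 in FEPS against K562 (3573), 639 in FEPS against Lucena 1 (2943), 86 with daunorubicin (5), 1 in the interaction (0) and 1781 in the overlap (678), and 11 lists in Lucena 1 (6) and 3 with vincristine (0). As deposited the median of all genes shifts by 1.16, 1.64, 0.47, -0.21, -1.09 and -0.89 in the 5 comparisons and the interaction, and relative to it these values keep the array levels that normalization removes. That shift turned ASAH1 in Lucena 1 (0.15), and in FEPS against K562 PDGFRB (0.65), CCNG1 (0.33), CDK1 (0.79), HSP90B1 (0.17), DDIT4 (0.185), EDEM1 (0.22), UQCRC2 (0.79), COX8A (0.875), PSAP (0.105), PRAME (0.615), RPL3 (0.53) and RPS7 (0.77). With arrays centred on their medians there were 17 genes with daunorubicin, 3 in the interaction, 10 lists in Lucena 1 and 3 with vincristine. Relative to all genes the centred and the deposited list values are the same by construction.

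The filter on mean signal left 0 genes with daunorubicin, and the mean of probe sets gave 11 and turned ASPM in FEPS against Lucena 1 (-0.746). Without shared-sequence suffixes 1 list was called with daunorubicin, and other probe sets turned TRDV3 (0.008) and HBB (0.285), ASPM (1.599, called) and FN1 (-0.634) in Lucena 1, ITGAM (0.779), ALAS2 (-0.031), BOK (-0.077), ZEB2 (-0.087), MAGEC2 (0.459) and TRDV3 (0.138) in FEPS against K562, and FCER1A (-0.167), ITGAM (0.983), STMN1 (-0.469), ASPM (-2.016, called) and MAGEC2 (0.046) in FEPS against Lucena 1. Fitting only the groups compared, with fewer arrays to estimate the spread, gave 744 genes in Lucena 1, 0 with daunorubicin and 1 in the interaction. An intensity trend gave 12 and 2 in the last pair. A 2-fold minimum gave 1334, 2863, 2442, 0, 5 and 0 genes.

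Replicate numbers deviated together between K562 and Lucena 1 with vincristine (r = 0.307 across genes), K562 and Lucena 1 without it (0.327) and both Lucena 1 groups (0.469), but not with FEPS (-0.079 to 0.036), so they pair no arrays over all groups. All 4 Lucena 1 arrays were closest to the array of the same number in the other Lucena 1 group. A replicate block gave 1644, 3951 and 3298 genes between lines, 0 with vincristine, 2 with daunorubicin and 1 in the interaction. The block for K562 and Lucena 1 only gave 2543 in Lucena 1 and 8 with daunorubicin, and the ACTB covariate 2706 in Lucena 1 and 2 lists with vincristine. Camera with an estimated correlation called 0 lists in every comparison, against 6, 10, 8, 0 and 2. The directional fry test called 10, 19, 13, 0 and 0, and the mixed test 23, 26, 25, 0 and 5, in that order.

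Without 1 array at a time, the lone array of its group being assumed to vary like the others, counts ranged from 503 (without Lucena 1 without drug replicate 1) to 1424 in Lucena 1, from 1428 (without FEPS without drug replicate 1) to 3534 in FEPS, and from 1324 (without the same array) to 3120 in FEPS against Lucena 1. They stayed at 0 with vincristine and ranged from 0 to 38 with daunorubicin, from 0 to 9 in the interaction (both highest without FEPS with drug replicate 1) and from 282 (without Lucena 1 without drug replicate 1) to 648 in the overlap. Called lists ranged from 5 to 7, 7 to 10, 5 to 9, 0 to 2 and 0 to 3. Without the dim K562 replicate 1 there were 1189 and 2902 genes against K562. The logarithm for linear values was not run, since the values are log2 already.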

Other observations

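All gene groups in this paragraph and the next were fixed before the data were examined, none was called by camera in the comparisons given, and counts are of members past the gene test. Of 23 megakaryocyte genes 2 rose and 0 fell in Lucena 1 (camera adjusted p = 0.31) and 3 rose and 0 fell in FEPS (camera adjusted p = 0.141), both against K562. The transcription factor NFE2, which acts in erythroid cells too, rose by 2.65 and 2.12, while THBS1, among the rises in FEPS, was under background in both groups. Of 20 granulocyte and monocyte genes 0 rose and 2 fell in Lucena 1 (camera adjusted p = 0.227), where lysozyme LYZ had -3.66, at least 4.63-fold lower. In FEPS 1 rose and 3 fell of the same list (camera adjusted p = 0.0696), which had a mean of -0.74 and a median of 0.03: LYZ (-4.13, at least 4.63-fold) and the Fc receptor FCGR2A (-4.40, at least 8.2-fold lower) fell, LYZ having -0.06 in Lucena 1 and -0.17 in FEPS on probe sets without shared-sequence suffixes, while CD14, among the rises, was under background in both groups. A pair of lists held markers of cell types that a culture of these lines should lack. Of 20 lymphoid markers 0 rose and 0 fell in Lucena 1 and 0 rose and 1 fell in FEPS, where CD3D had -1.64 (camera adjusted p = 0.975 and 0.681). Of 19 fibroblast and epithelial markers 0 rose and 1 fell in Lucena 1 and 0 rose and 2 fell in FEPS (camera adjusted p = 0.975 and 0.912), with the collagen gene COL6A3 at -1.62 and -2.32, at least 2.55-fold and 2.55-fold.

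For topoisomerases and DNA repair 0 rose and 1 fell of 32 in Lucena 1, where the end-joining ligase LIG4 had -2.21, and 2 rose and 0 fell in FEPS, TOP3A (1.02, or 0.63 and not called on probe sets without shared-sequence suffixes) and BRCA1 (0.94), with camera adjusted p = 0.227 and 0.539. Of 39 mitosis genes 2 rose and 1 fell in Lucena 1, with TACC3 (1.39) and the checkpoint kinase BUB1 (0.89) higher and ASPM the fall, which was a called rise on probe sets without shared-sequence suffixes (1.60, adjusted p = 0.0203), and 2 rose and 1 fell in FEPS, with BIRC5 (1.23) and CDC20 (0.95) higher (camera adjusted p = 0.719 and 0.566). Of 40 respiratory chain genes 0 rose and 0 fell in Lucena 1 and 1 rose and 2 fell in FEPS, NDUFA10 (1.27) being the rise (camera adjusted p = 0.644 and 0.343). In the lysosome list 3 rose and 6 fell of 34 in FEPS (camera adjusted p = 0.5), where the proteases CTSS (-4.76, at least 12.2-fold lower) and CTSH (-2.66) fell and the channel MCOLN1 (2.02) rose. Of 16 cancer-testis antigens, several of them near-identical copies, 1 rose and 0 fell in Lucena 1, SSX1 at 2.60 (at least 4.82-fold), and 2 rose and 3 fell in FEPS, with MAGEC1 at -5.03 (at least 12.3-fold) and LAGE3 at 1.22 (camera adjusted p = 0.975 and 0.566). On probe sets without shared-sequence suffixes the cancer-testis gene MAGEC2 had 0.459 in FEPS against K562.

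A hypothesis, formed after the flanking genes of ABCB1 were seen, is that other stretches of neighbouring genes also changed together, and of its tests the choice to leave chromosome 7 out was made after the result was seen. Over 11922 expressed genes without chromosome 7, the log2 differences of genes 5 places apart correlated across genes at 0.054 for Lucena 1 against K562, 0.042 for FEPS against K562 and 0.0556 for FEPS against Lucena 1. None of 1000 shuffles of gene order reached these values in any of the 3 comparisons, where the highest were 0.0289, 0.0332 and 0.0279. Neighbouring genes are not independent replicates, and the correlations are small. With vincristine 642 of 1000 shuffles were as high as the observed -0.0036, and with daunorubicin 24 of 1000 were as high as 0.0183. For genes 1 place apart, 100 of 1000 were as high as 0.0117 with vincristine and 0 of 1000 as high as 0.0497 with daunorubicin. At 20 places apart, 2 of 1000 were as high as 0.0265 with daunorubicin. Neighbouring genes thus also changed together between the FEPS groups, which are of the same line.

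The stretches given here are examples chosen after their values were seen. Higher and lower refer here to the sign of the fitted difference, whether or not a gene passed the test. The genes that name the ends of a stretch need not share its direction: PHTF2 (-2.06) and SAMD9L (-1.06) were lower in Lucena 1 than in K562. In Lucena 1 against K562, 24 of 30 expressed genes from PHTF2 to SAMD9L on chromosome 7 were higher (median 1.42) and 19 of 21 from JAK2 to MTAP on chromosome 9 were lower (median -1.08). The histone genes of chromosome 6 from H2AC6 to H4C8 formed a further stretch, with 10 of 11 higher (median 1.12). In FEPS against Lucena 1, 28 of 30 from VPS4B to PARD6G on chromosome 18 (median 1.43) and 16 of 16 from CAT to C11orf96 on chromosome 11 (median 1.23) were higher. In FEPS against K562, 15 of 20 from RPL13AP17 to CDK14 on chromosome 7 (median 1.41) and 13 of 15 from ZNF516 to PARD6G on chromosome 18 (median 1.40) were higher, and 11 of 15 from PYGO1 to CCNB2 on chromosome 15 were lower (median -1.54). Both chromosome 7 stretches hold ABCB1, several of its flanking genes and CD36, so they are not separate from the ABCB1 locus. Their highest median over 11 adjacent expressed genes, ABCB1 included, was 1.934 in Lucena 1 and 2.077 in FEPS. The highest in 100 shuffles of gene order was 1.197 and 1.64. With daunorubicin in FEPS, 11 of 13 from ADHFE1 to LACTB2 on chromosome 8 were lower (median -0.57), and only PTTG3P among them was called. Gains and losses of chromosome segments in the resistant lines are a candidate explanation for such stretches, as the lowest of the 3 correlations, 0.042, was above every shuffle, but copy number was not measured and shared regulation of neighbours, as in the histone cluster, would give the same picture.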
